A study of Rattus norvegicus with 20 samples.

How the data were processed

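Gene expression was measured in liver RNA of male rats on Affymetrix arrays, 1 array per sample: 5 arrays for the vehicle group and 3 for each of the 5 dosed groups, 20 in all. Per the labels' protocols, pieces of the left liver lobe were frozen, total RNA was isolated from each and amplified, and biotin-labelled RNA was hybridised. The deposited values are log2 expression per probe set, summarised with RMA per the submitters' processing notes. RMA in general corrects the background, normalizes quantiles across arrays and summarises the probes of a set by median polish, so differences in total RNA between samples are removed and low signals are compressed. The version and settings of RMA, scan dates and batches are not given in the sources used here. The log2 scale was inferred from the values, which have nearly equal quartiles on every array, and the array medians lay between 6.31 and 6.39. No 2 arrays shared more than 0.0226% of their values, so no array was treated as a repeat of another.

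Of 31099 probe sets in the table, 57 control probe sets were set aside and 31042 analysed. GEO's platform annotation, which can be old, gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780; 20758 of the first kind matched a current RefSeq gene by gene ID (assembly GRCr8, used for names only), and 0 symbols changed. Probe sets with several symbols or none were left out of the gene tests and name no gene here. Each of the 14217 genes was represented by its probe set with the highest mean over all arrays; 4525 genes had more than 1. Cyp2b1, Cyp2b2 and Ugt1a1 were not analysed here as single genes. The 3' minus 5' differences of the Gapdh, beta-actin and hexokinase control probe sets served as signs of RNA quality.

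Each dose was compared with vehicle in 1 linear model of the 6 dose groups over all arrays, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The groups share 1 estimate of the spread, since 3 arrays give a poor estimate of their own. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05 with no filter on fold change. The 881 and 440 mg/kg groups were compared in the same model. The trend was fitted in a model with the dose step, 0 to 5, as 1 numeric term. "Rose" and "fell" are used for called genes, and adjusted p-values of genes are limma's. Signal was not filtered in the gene tests. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

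The comparisons, tests, gene lists and rule for named genes, and the alternatives apart from those called added, were fixed before the data were examined. The rule named the 10 genes that rose and the 10 that fell most at 881 mg/kg among called genes whose arrays all lay beyond all vehicle arrays, 5 in each direction at every other dose and between 440 and 881 mg/kg, and for the trend the 5 of each direction with the smallest p. It added from each list up to 4 called members with the largest change at 881 mg/kg, and a set of genes of foreign-compound, lipid and thyroid biology whatever their result. Uncharacterised entries were counted and not named: 12 of the 1525 eligible genes that rose at 881 mg/kg and 8 of the 745 that fell. Of 127 genes the rule named, 30 had several probe sets, and none of those called had another probe set called the opposite way. Some had another that was not called at 881 mg/kg when every probe set was tested. Among these were Kif11 (log2 change 0.088 on that probe set), Lss (0.41), Mdm2 (-0.088), Ctsc (0.25), Per3 (-0.011) and Topbp1 (0.21).

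The 31 gene lists were CAR and PXR targets, AhR targets, NRF2 targets, PPAR alpha targets, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acid synthesis and transport, carboxylesterases and other serine hydrolases, thyroid hormone response, acute phase and complement, heat shock and protein folding, endoplasmic reticulum and integrated stress response, p53 response, cell cycle, heme synthesis, male-biased and female-biased rat liver genes, circadian clock, gluconeogenesis and fasting response, amino acid breakdown and urea cycle, glutathione transferases, glucuronosyltransferases and sulfotransferases, and markers of hepatocytes, pericentral and periportal hepatocytes, Kupffer cells and macrophages, stellate cells and fibroblasts, endothelial cells, bile duct cells, lymphocytes and blood cells. Of 592 listed members, 513 were measured. Each list was tested with limma's camera at a preset correlation of 0.01 at the 5 doses and for the trend, and the 186 p-values were adjusted together. Camera was repeated with the correlation estimated for each list, and fry was run as well; fry asks whether a list's genes move on balance one way and does not compare them with other genes. Members were counted by the gene test over all genes and with p-values adjusted over the list alone.

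The model was tested on simulated data built from the measured means and spreads over all 14217 genes. For 881 mg/kg against vehicle it recovered 65.7% of genes changed by 0.5 (log2), 97.0% of those changed by 1 and 100% of those changed by 2, and 7 of 182 calls were false. For the trend it recovered 80.6% of genes changed by 0.1 per step and 100% of those changed by 0.2 or 0.4, and 12 of 199 calls were false. The simulated genes varied independently, with normal noise and 1 spread per gene on all arrays. Correlated genes and arrays of poorer RNA quality were not simulated, so these shares need not hold for the measured data.

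Alternatives were another normalization or centring of the arrays, a minimum log2 of 6 in at least 1 group, other settings of eBayes, array quality weights, the replicate number as a block, the mean of a gene's probe sets, every probe set counted, a 1.5-fold minimum, only the 2 groups compared, dose in mg/kg for the trend, and leaving out each array, the highest dose group or the vehicle group. Added after the data were seen were the beta-actin difference as a covariate, 881 mg/kg replicate 2 left out of the shared model, and comparisons between dosed groups. For the correlation of changes at 440 and 881 mg/kg, which share the vehicle arrays, unchanged groups were simulated 100 times and the vehicle arrays were split in 20 ways.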

Results

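Liver RNA of male Harlan Sprague Dawley rats was profiled on 20 Affymetrix expression arrays after gavage with triphenyl phosphate, an aryl phosphate ester used as a flame retardant and plasticiser. The vehicle group (0 mg/kg, corn oil) held 5 arrays, and the 55, 110, 220, 440 and 881 mg/kg groups held 3 arrays each. The rats received 4 daily doses, and liver was taken on day 5. The study asked how the liver transcriptome changes with dose over this short exposure. The sample labels give the dose next to the highest as 440 mg/kg and the design text gives 441 mg/kg; the label's value is used here. The treatment text speaks of fewer dose groups than it lists doses, and of equal groups of 3 rats, whereas the vehicle group holds 5 arrays. The labels do not tie each array to a separate animal, so the p-values measure the spread between these samples, which may in part be technical. The number of arrays limits the precision: the standard error of a log2 change against vehicle had a median of 0.10 over the 14217 genes tested.

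Array medians lay between 6.31 and 6.39 on the log2 scale. The median correlation of an array with the others was 0.980 for 881 mg/kg replicate 2 and 0.990 to 0.994 for every other array. The 3' end of the Gapdh control gene read 5.24 higher (log2) than its 5' end on 881 mg/kg replicate 2, against 0.81 to 1.64 on the other arrays. For beta-actin this difference was 3.47 against 1.67 to 2.72, and for the hexokinase control probe sets it was 1.47 against 1.54 to 2.05. Counts and gene groups at 881 mg/kg are therefore also given without that array.

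**Figure D1:**
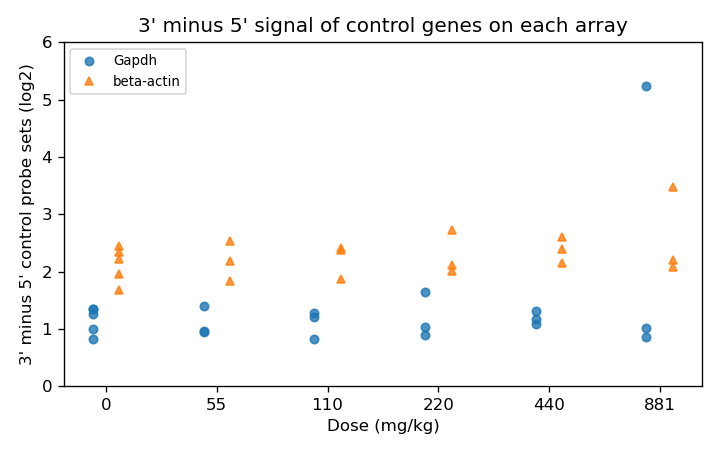
Signal of the 3' minus the 5' control probe sets (log2, vertical axis) of Gapdh (circles) and beta-actin (triangles) on each of the 20 arrays, by dose in mg/kg (horizontal axis). At 881 mg/kg, replicate 2 lies at 5.24 for Gapdh and 3.47 for beta-actin, above every other array.

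At 881 mg/kg the genes with the largest increases included enzymes and transporters that handle foreign compounds. Ces2c, a carboxylesterase, rose 16.3-fold (log2 change 4.03 ± 0.21, SE; 12.86 ± 0.42 against 8.83 ± 0.074, mean ± SD of 3 and 5 arrays, adjusted p = 1.01e-09). Abcc3, an efflux transporter of conjugates, rose 12.7-fold (3.67 ± 0.33, adjusted p = 1.31e-06), and the aldo-keto reductase Akr1b7 rose 29.0-fold (4.86 ± 0.72, adjusted p = 0.000146), with levels of 9.56 ± 1.23 against 4.70 ± 0.21. Slc6a6, the taurine transporter, fell by 3.97 ± 0.24 on the log2 scale (6.33 ± 0.22 against 10.30 ± 0.27, adjusted p = 1.26e-08). Scd, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, fell by 3.47 ± 0.54 (adjusted p = 0.000236).

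In all, 2767 of 14217 genes (19.5%) changed at 881 mg/kg in limma's test against vehicle, 1810 rising and 957 falling, or 1490 and 1345 with each array centred on its median. The other genes among the 10 largest increases were led by the clock-output transcription factor Dbp (3.83 ± 0.27, limma adjusted p = 9.60e-08). The rest were the glutathione transferases Gsta3 (2.72 ± 0.43) and Gstp1 (2.22 ± 0.26), Cyp1a1 (2.60 ± 0.34), Myc (2.16 ± 0.34), Cryl1 (2.12 ± 0.21) and the aldo-keto reductase Akr1b8 (2.12 ± 0.42). Among the 10 largest decreases were also Stac3 (-3.54 ± 0.45, adjusted p = 4.00e-05), Dhrs7l1 (-2.95 ± 0.45), the clock transcription factor Npas2 (-2.60 ± 0.24), the immediate-early gene Egr1 (-2.42 ± 0.29), Serpina7 (-2.34 ± 0.31), which encodes thyroxine-binding globulin, Nim1k (-2.31 ± 0.28), the beta-globin gene Hbb (-2.23 ± 0.36) and the lysyl oxidase gene Lox (-2.38 ± 0.68). The rule that named these genes required all 3 dosed arrays to lie beyond all 5 vehicle arrays. Lox lost its call without 881 mg/kg replicate 2 (adjusted p = 0.0808) and with the beta-actin difference as a covariate (0.0634); without that array the changes were 4.33 for Akr1b7, 1.22 for Akr1b8, -2.67 for Scd and -1.84 for Hbb, all still called.

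Targets of CAR and PXR, targets of NRF2 and glutathione transferases passed upward as lists. Of the targets of the nuclear receptors CAR and PXR, 16 of 24 measured members rose, 16 adjusted over the list alone and 14 without 881 mg/kg replicate 2, with a median log2 change of 0.67. The camera test of this list gave adjusted p = 7.16e-11, and adjusted p = 0.0689 with an estimated correlation. Besides Ces2c, Abcc3 and Gsta3, the list held Alas1 (1.70 ± 0.23), the rate-limiting enzyme of heme synthesis, and Cyp3a23-3a1 (1.18 ± 0.14) rose as well. Of the targets of NRF2, the regulator of the oxidative stress response, 15 of 22 measured members rose, 17 adjusted over the list alone and 15 without 881 mg/kg replicate 2, and the list's median was 0.996 (adjusted p = 3.39e-12, and adjusted p = 0.0689 with an estimated correlation). These included Gstp1, Akr1b8, Akr7a3 (1.86 ± 0.29), Me1 (1.81 ± 0.24) and Nqo1 (1.79 ± 0.25). Of the glutathione transferases, 11 of 19 measured members rose, 12 adjusted over the list alone (where 1 fell) and 10 without 881 mg/kg replicate 2 (adjusted p = 9.25e-05, and adjusted p = 0.169 with an estimated correlation). Gsta4 (1.48 ± 0.11, adjusted p = 1.07e-07) and Gstt3 (1.87 ± 0.27) were among those that rose. Glucuronosyltransferases and sulfotransferases did not pass as a list (adjusted p = 0.175). Among them 8 of 17 measured members rose and 3 fell, 8 and 4 adjusted over the list alone and 6 and 3 without 881 mg/kg replicate 2. Of these, Ugt2b1 (1.61 ± 0.13), Ugt2b7 (1.22 ± 0.28) and Ugt2b10 (1.12 ± 0.10) rose, and the sulfotransferase Sult1c3 (-1.08 ± 0.11) fell.

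Cyp1a1 and Cyp1a2, both targets of the aryl hydrocarbon receptor, moved apart. Cyp1a1 rose by 2.60 and Cyp1a2 (-0.64 ± 0.085, adjusted p = 5.53e-05) fell. Of the AhR targets, 2 of 8 measured members rose and 1 fell, 2 and 2 adjusted over the list alone and 2 and 1 without 881 mg/kg replicate 2, and the list did not pass (adjusted p = 0.641). Its median was -0.17 and its mean 0.35. Of the carboxylesterases and other serine hydrolases, 4 of 19 measured members rose and 2 fell, 4 and 2 adjusted over the list alone and 1 and 2 without 881 mg/kg replicate 2, and the list did not pass either (adjusted p = 0.282). In it Ces1d (-0.70 ± 0.13) and the hepatic lipase gene Lipc (-0.50 ± 0.11) fell, and Bche, the butyrylcholinesterase gene, measured -0.012 ± 0.12 (adjusted p = 0.959). The lysosomal lipase gene Lipa (0.54 ± 0.15) rose but lost its call without 881 mg/kg replicate 2 (adjusted p = 0.116).

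Genes of cholesterol synthesis passed upward as a list. Of the cholesterol synthesis list, 13 of 20 measured members rose, 17 adjusted over the list alone and 9 without 881 mg/kg replicate 2 (adjusted p = 6.26e-07, and adjusted p = 0.361 with an estimated correlation). The median was 0.66. The largest changes were those of Mvd (1.18 ± 0.25), Acat2 (1.10 ± 0.29), Msmo1 (1.10 ± 0.21) and Lss (1.05 ± 0.19). Of the genes of fatty acid and triglyceride synthesis, 9 of 24 measured members rose and 3 fell, 9 and 3 adjusted over the list alone and 8 and 3 without 881 mg/kg replicate 2 (adjusted p = 0.0304, and adjusted p = 0.394 with an estimated correlation). Without 881 mg/kg replicate 3 the list's adjusted p was 0.304. The elongase Elovl6 (1.80 ± 0.33) and the fatty acid synthase Fasn (1.15 ± 0.27) rose, while Scd and Lpin1 (-1.24 ± 0.25) fell. Of the bile acid list, 4 of 22 measured members rose and 7 fell, 5 and 7 adjusted over the list alone and 3 and 5 without 881 mg/kg replicate 2. The list did not pass (adjusted p = 0.0892), and its median was -0.14 and its mean 0.024. The sterol exporters Abcg5 (-1.66 ± 0.29) and Abcg8 (-1.50 ± 0.26) fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose (1.18 ± 0.38, adjusted p = 0.0364). This call was lost without vehicle replicate 1 (adjusted p = 0.0782), vehicle replicate 2 (0.0771), 881 mg/kg replicate 1 (0.0576) or 881 mg/kg replicate 2 (0.169), and under 4 other settings (0.0642 to 0.117).

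Targets of PPAR alpha and genes of amino acid breakdown were more often lower than higher. Of the targets of PPAR alpha, the receptor that drives fatty acid oxidation, 2 of 33 measured members rose and 12 fell, 5 and 13 adjusted over the list alone and 1 and 9 without 881 mg/kg replicate 2 (adjusted p = 0.00298, and adjusted p = 0.373 with an estimated correlation). The lipid droplet gene Plin2 (-1.80 ± 0.19, adjusted p = 6.05e-06), Angptl4 (-1.24 ± 0.27) and Pdk4 (-1.22 ± 0.27) fell, while Cyp4a8 (1.91 ± 0.31) rose. Cyp4a1 fell by 0.56 ± 0.17. Its call was lost without vehicle replicate 3 (adjusted p = 0.0533), vehicle replicate 4 (0.0561), 881 mg/kg replicate 1 (0.110) or 881 mg/kg replicate 3 (0.0846). Of the genes of amino acid breakdown and the urea cycle, 2 of 35 measured members rose and 14 fell, 4 and 15 adjusted over the list alone and 1 and 10 without 881 mg/kg replicate 2 (adjusted p = 0.00128, and adjusted p = 0.218 with an estimated correlation). Ornithine aminotransferase Oat (-1.99 ± 0.24), Got1 (-1.24 ± 0.22) and kynureninase Kynu (-1.17 ± 0.11) were among those that fell. Of the gluconeogenesis and fasting list, 4 of 15 measured members fell, 5 adjusted over the list alone and 2 without 881 mg/kg replicate 2 (adjusted p = 0.0222, and adjusted p = 0.273 with an estimated correlation), pyruvate carboxylase Pc (-0.55 ± 0.085) among them.

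Clock genes changed in both directions. Of the clock list, 6 of 17 measured members rose and 2 fell, 8 and 3 adjusted over the list alone and 6 and 2 without 881 mg/kg replicate 2 (adjusted p = 0.0236, and adjusted p = 0.167 with an estimated correlation). Dbp and Per3 (2.04 ± 0.23), which belong to the negative arm and output of the clock, rose, and Bmal1 (-1.84 ± 0.23, adjusted p = 2.90e-05) and Npas2, which belong to its positive arm, fell. Of the cell cycle genes, 13 of 31 measured members rose, 18 adjusted over the list alone and 23 without 881 mg/kg replicate 2 (adjusted p = 6.11e-07, and adjusted p = 0.310 with an estimated correlation). The list's median was 0.64, or 1.04 without that array. The proliferation marker Mki67 (1.68 ± 0.35, adjusted p = 0.00269) and the mitotic kinesin Kif11 (1.02 ± 0.15, adjusted p = 0.000117) rose. Another probe set of Kif11 measured 0.088 and was not called. Mki67 read 7.44 and 7.27 (log2) on 881 mg/kg replicates 1 and 3 and 5.77 on replicate 2, against 4.64 to 5.97 on the vehicle arrays.

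The p53, endoplasmic reticulum stress, acute phase, heat shock, heme and thyroid hormone lists did not pass at 881 mg/kg. Of the p53 list, 5 of 15 measured members rose and 3 fell, 6 and 4 adjusted over the list alone and 6 and 3 without 881 mg/kg replicate 2, with a median of 0.24 and a mean of -0.018 (adjusted p = 0.371). Cdkn1a, an inhibitor of cyclin-dependent kinases, fell by 1.93 ± 0.22 (adjusted p = 1.21e-05). Rprm (-1.73 ± 0.33) and Phlda3 (-0.84 ± 0.14) fell too, and Mdm2 (0.84 ± 0.10) rose. Of the genes of the endoplasmic reticulum and integrated stress response, 6 of 26 measured members rose and 2 fell, 6 and 2 adjusted over the list alone and 4 and 1 without 881 mg/kg replicate 2 (adjusted p = 0.194). The serine synthesis gene Psat1 (1.56 ± 0.34) and Gdf15 (0.58 ± 0.15) rose, and Ddit3 measured -0.044 ± 0.15 (adjusted p = 0.867). In the acute phase list, 3 of 23 measured members rose and 1 fell, 4 and 3 adjusted over the list alone and 3 that rose without 881 mg/kg replicate 2 (adjusted p = 0.868), with Orm1 (0.71 ± 0.16) and Hamp (0.47 ± 0.091) higher. In the heat shock list, 2 of 10 measured members rose, 3 adjusted over the list alone and 1 without 881 mg/kg replicate 2 (adjusted p = 0.492). In the heme synthesis list, 2 of 10 measured members rose and 1 fell, 2 and 1 adjusted over the list alone and 2 that rose without 881 mg/kg replicate 2 (adjusted p = 0.141), where Alas1 and the heme oxygenase Hmox1 (1.74 ± 0.17, adjusted p = 2.77e-06) rose. In the thyroid hormone list, 5 of 14 measured members rose and 1 fell, 5 and 1 adjusted over the list alone and 3 and 1 without 881 mg/kg replicate 2, with a median of -0.082 and a mean of 0.13 (adjusted p = 0.649). Serpina7 fell and Thrsp (1.07 ± 0.22) rose, the latter not called when its probe sets were averaged (0.78, adjusted p = 0.171).

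Genes with a male bias in rat liver fell more often than they rose. Of the male-biased list, 1 of 18 measured members rose and 8 fell, 1 and 10 adjusted over the list alone and 1 and 7 without 881 mg/kg replicate 2 (adjusted p = 0.000113, and adjusted p = 0.191 with an estimated correlation). Stac3, Obp3 (-2.01 ± 0.26) and the transporter Slc22a8 (-1.54 ± 0.15) fell, and Hsd17b2 (1.71 ± 0.20), which inactivates sex steroids, rose. The male-specific Cyp2c11 fell (-0.41 ± 0.10, adjusted p = 0.00855), a call lost without 881 mg/kg replicate 2 (adjusted p = 0.0790). Of the female-biased list, 4 of 14 measured members rose and 1 fell, 4 and 1 adjusted over the list alone and 3 that rose without 881 mg/kg replicate 2. The list did not pass (adjusted p = 0.182). Akr1b7 and the sulfotransferase Sult2a6 (1.19 ± 0.23) rose.

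Marker lists of Kupffer, stellate, endothelial, lymphocyte and blood cells passed downward at 881 mg/kg, and that of bile duct cells did not pass. Of the Kupffer cell and macrophage markers, 11 of 14 measured members fell, 13 adjusted over the list alone and 5 without 881 mg/kg replicate 2 (adjusted p = 5.37e-07, and adjusted p = 0.278 with an estimated correlation). The median was -0.70 both with and without that array. Of the stellate cell and fibroblast markers, 9 of 18 measured members fell, 11 adjusted over the list alone (where 1 rose) and 4 without 881 mg/kg replicate 2 (adjusted p = 1.20e-05, and adjusted p = 0.229 with an estimated correlation). Medians with and without the array were -0.45 and -0.37. Of the endothelial markers, 4 of 15 measured members fell, 6 adjusted over the list alone and 1 without 881 mg/kg replicate 2 (adjusted p = 0.00127, and adjusted p = 0.530 with an estimated correlation). Their medians were -0.45 and -0.43. The complement gene C1qa (-0.88 ± 0.19, adjusted p = 0.00311), the collagen Col3a1 (-0.91 ± 0.20), Ecm1 (-0.89 ± 0.16) and Egfl7 (-0.33 ± 0.090) fell. Without 881 mg/kg replicate 2 the changes of C1qa and Col3a1 were -0.63 and -0.68. Of the lymphocyte markers, 3 of 14 measured members fell, 4 adjusted over the list alone and 1 without 881 mg/kg replicate 2 (adjusted p = 0.00506, and adjusted p = 0.273 with an estimated correlation). Of the blood cell markers, 2 of 10 measured members fell, 2 adjusted over the list alone and 2 without 881 mg/kg replicate 2 (adjusted p = 0.0190, and adjusted p = 0.253 with an estimated correlation). The blood genes that fell were Hbb and Alas2 (-1.75 ± 0.29). Without 881 mg/kg replicate 3 the lymphocyte list reached an adjusted p of 0.0525 and the blood list 0.0511. Bile duct markers did not pass (adjusted p = 0.649), with Epcam (0.86 ± 0.14) the 1 member of 11 that rose, both over all genes and adjusted over the list alone. Of the hepatocyte markers, 1 of 14 measured members rose and 2 fell, 1 and 2 adjusted over the list alone and 1 that rose without 881 mg/kg replicate 2 (adjusted p = 0.175). Apoa1 (0.34 ± 0.070) rose. Pericentral hepatocyte markers fell as a list (adjusted p = 0.000332, and adjusted p = 0.129 with an estimated correlation). In it 1 of 13 measured members rose and 6 fell, 1 and 7 adjusted over the list alone and 8 that fell without 881 mg/kg replicate 2. Glutamine synthetase Glul (-0.75 ± 0.13) and Gulo (-0.72 ± 0.11) fell. Periportal markers did not pass (adjusted p = 0.321). Among them 3 of 15 measured members rose and 5 fell, 4 and 6 adjusted over the list alone and 2 and 3 without 881 mg/kg replicate 2. Hal (-0.67 ± 0.11) and Cyp2f4 (-0.64 ± 0.12) fell and Ctsc (0.48 ± 0.11) rose.

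At 881 mg/kg, 17 of the 31 lists passed camera's test, 7 of them up and 10 down. None passed with an estimated correlation between the members; the lowest adjusted p was then 0.0689. The fry test, which asks whether a list's genes move on balance one way without setting them against other genes, passed 22 lists but not the endothelial 1 (adjusted p = 0.114). With a minimum log2 of 6, the calls of the fatty acid synthesis (adjusted p = 0.106), clock (0.0637) and lymphocyte lists (0.0764) were lost. The gluconeogenesis list lost its call with the beta-actin difference as a covariate (adjusted p = 0.0565) and the blood list with quantile normalization run again (0.0789). Without 881 mg/kg replicate 2, 1643 genes were called, 1084 rising and 559 falling, 1412 of them also called with all arrays, and 17 lists passed. An added requirement of a 1.5-fold change left 719 genes.

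**Figure D2:**
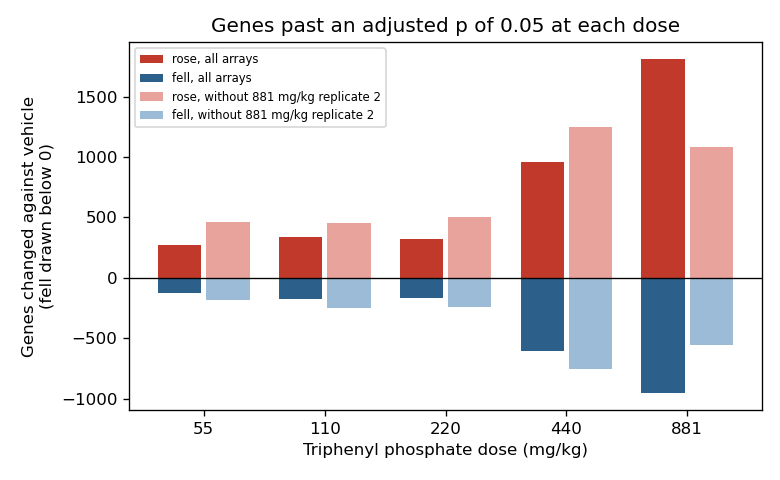
Number of genes past an adjusted p of 0.05 against vehicle at each dose (mg/kg, horizontal axis), with rising genes drawn above 0 and falling genes below, for all arrays (dark bars) and without 881 mg/kg replicate 2 (light bars). The count was 400 at 55 mg/kg, 1570 at 440 mg/kg and 2767 at 881 mg/kg, or 1643 without that array.

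At 440 mg/kg, Ces2c rose 10.3-fold (log2 change 3.37 ± 0.21, SE, 3 against 5 arrays, adjusted p = 1.19e-08) and Abcc3 9.82-fold (3.30 ± 0.33). The clock-output gene Dbp (4.50 ± 0.27, adjusted p = 1.19e-08), Noct (2.64 ± 0.35), a rhythmic gene that encodes nocturnin, and Nfe2 (2.58 ± 0.42) completed the 5 largest increases. The 5 largest decreases were those of the taurine transporter Slc6a6 (-3.86 ± 0.24, adjusted p = 1.37e-08), Scd (-3.40 ± 0.54), Pdk4 (-3.12 ± 0.27), which restrains glucose oxidation, Egr1 (-2.95 ± 0.29) and Stac3 (-2.81 ± 0.45). Npas2 (-2.58), Bmal1 (-2.43) and Nfil3 (-2.10) fell, and Per3 (2.33) and Nr1d1 (1.62) rose. Cyp1a1 rose (1.61) and Cyp1a2 fell (-0.74), as at the highest dose, and Gstp1 (1.56) and Cyp3a23-3a1 (1.04) rose.

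Of the CAR and PXR targets, 14 of 24 measured members rose and 1 fell, 16 and 1 adjusted over the list alone at 440 mg/kg (adjusted p = 3.42e-09, and adjusted p = 0.0689 with an estimated correlation). Of the NRF2 targets, 10 of 22 measured members rose and 1 fell, 14 and 1 adjusted over the list alone (adjusted p = 2.34e-07, and adjusted p = 0.129 with an estimated correlation). Of the cholesterol synthesis list, 8 of 20 measured members rose, 12 adjusted over the list alone (adjusted p = 3.47e-05, and adjusted p = 0.415 with an estimated correlation). Of the glutathione transferases, 9 of 19 measured members rose, 10 adjusted over the list alone (adjusted p = 2.36e-05, and adjusted p = 0.129 with an estimated correlation). Genes of the endoplasmic reticulum and integrated stress response passed as a list at this dose, where 8 of 26 measured members rose, 10 adjusted over the list alone (adjusted p = 5.03e-05, and adjusted p = 0.229 with an estimated correlation). Of the clock list, 9 of 17 measured members rose and 5 fell, 10 and 5 adjusted over the list alone (adjusted p = 0.00127, and adjusted p = 0.0689 with an estimated correlation). PPAR alpha targets went down on balance, where 3 of 33 measured members rose and 9 fell, 4 and 10 adjusted over the list alone (adjusted p = 0.00311, and adjusted p = 0.373 with an estimated correlation). Male-biased genes went down as well, where 1 of 18 measured members rose and 9 fell, 2 and 9 adjusted over the list alone (adjusted p = 0.000771, and adjusted p = 0.229 with an estimated correlation). Pericentral markers did too, where 5 of 13 measured members fell, 8 adjusted over the list alone (adjusted p = 0.000108, and adjusted p = 0.129 with an estimated correlation).

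The Kupffer, stellate and endothelial lists passed downward at 440 mg/kg too, where the beta-actin 3' minus 5' difference was 2.14 to 2.61. Of the Kupffer cell and macrophage markers, 4 of 14 measured members fell, 14 adjusted over the list alone (median log2 change -0.58, adjusted p = 1.19e-06, and adjusted p = 0.298 with an estimated correlation). Of the stellate cell and fibroblast markers, 7 of 18 measured members fell, 12 adjusted over the list alone (where 1 rose) (median -0.57, adjusted p = 5.09e-07, and adjusted p = 0.191 with an estimated correlation). Of the endothelial markers, 7 of 15 measured members fell, 11 adjusted over the list alone (median -0.65, adjusted p = 3.93e-05, and adjusted p = 0.394 with an estimated correlation). The list of glucuronosyltransferases and sulfotransferases (adjusted p = 0.0332, and adjusted p = 0.229 with an estimated correlation) passed upward. Downward passed those of bile acids (adjusted p = 0.0443, and adjusted p = 0.240 with an estimated correlation), gluconeogenesis (adjusted p = 0.0190, and adjusted p = 0.255 with an estimated correlation), amino acid breakdown (adjusted p = 0.0236, and adjusted p = 0.346 with an estimated correlation) and lymphocytes (adjusted p = 0.0147, and adjusted p = 0.316 with an estimated correlation). These 5 each lost their call without 1 or more single arrays, and all but gluconeogenesis under other settings too. In fry the endothelial list did not pass (adjusted p = 0.0588). In all, 1570 genes changed, 961 rising and 609 falling in limma's test. Without 440 mg/kg replicate 2 the count was 867, and without replicate 3 it was 945.

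At 220 mg/kg, Dbp (3.77 ± 0.27, SE, 3 against 5 arrays, adjusted p = 3.78e-07), Abcc3 (2.49 ± 0.33), the stress-induced gene Ddit4 (2.35 ± 0.41), Hsd17b2 (2.25 ± 0.20) and Ces2c (2.14 ± 0.21) showed the 5 largest increases. The 5 largest decreases were those of Egr1 (-2.88 ± 0.29), Scd (-2.59 ± 0.54), Slc6a6 (-2.58 ± 0.24), the tubulin gene Tubb2a (-1.96 ± 0.24) and the cell cycle inhibitor Cdkn1a (-1.89 ± 0.22). Scd lost its call without 220 mg/kg replicate 1 (adjusted p = 0.0592). Cyp3a23-3a1 rose by 0.65, and Cyp1a2 (-0.49) and Oat (-1.33) fell, while Cyp1a1 was not called.

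Of the CAR and PXR targets, 8 of 24 measured members rose, 13 adjusted over the list alone (where 2 fell) at 220 mg/kg (adjusted p = 6.98e-07, and adjusted p = 0.129 with an estimated correlation). Of the NRF2 targets, 3 of 22 measured members rose, 9 adjusted over the list alone (adjusted p = 5.03e-05, and adjusted p = 0.219 with an estimated correlation). In the clock list, 8 of 17 measured members rose and 4 fell, 10 and 4 adjusted over the list alone (adjusted p = 0.00169, and adjusted p = 0.0689 with an estimated correlation). In the endoplasmic reticulum and integrated stress response list, 4 of 26 measured members rose, 12 adjusted over the list alone (where 1 fell) (adjusted p = 9.25e-05, and adjusted p = 0.240 with an estimated correlation). Of the PPAR alpha targets, 4 of 33 measured members fell, 12 adjusted over the list alone (where 2 rose) (adjusted p = 5.03e-05, and adjusted p = 0.240 with an estimated correlation). Of the stellate cell markers, 1 of 18 measured members fell, 2 adjusted over the list alone (adjusted p = 0.00178, and adjusted p = 0.373 with an estimated correlation). Limma called 0 of the Kupffer cell and endothelial markers (1 and 2 were lower at an unadjusted p under 0.05), yet both lists passed downward, with medians of -0.35 (adjusted p = 0.000130, and adjusted p = 0.394 with an estimated correlation) and -0.24 (adjusted p = 0.0137, and adjusted p = 0.644 with an estimated correlation). The endothelial list lost its call without vehicle replicate 1 (adjusted p = 0.0559) or 220 mg/kg replicate 2 (0.124) or 3 (0.0541), and with the beta-actin difference as a covariate (0.0640). In fry the Kupffer (adjusted p = 0.151), stellate (0.111) and endothelial lists (0.388) did not pass. Glutathione transferases passed upward (adjusted p = 0.00170, and adjusted p = 0.229 with an estimated correlation). Pericentral (adjusted p = 0.00341, and adjusted p = 0.199 with an estimated correlation), male-biased (adjusted p = 0.0305, and adjusted p = 0.394 with an estimated correlation), heat shock (adjusted p = 0.0197, and adjusted p = 0.394 with an estimated correlation) and gluconeogenesis genes (adjusted p = 0.0390, and adjusted p = 0.310 with an estimated correlation) passed downward, and the last 3 lists lost their call without some single arrays, under other settings and in fry. In all, 488 genes changed in limma's test, 320 rising and 168 falling. The count was 204 without 220 mg/kg replicate 2, 213 without replicate 3, 298 without replicate 1 and 292 without vehicle replicate 4, and 748 with 881 mg/kg replicate 2 left out of the shared estimate of the spread.

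At 110 mg/kg the 5 largest increases were led by Dbp (log2 change 4.07 ± 0.27, SE, limma adjusted p = 9.95e-08) and the immediate-early phosphatase Dusp1 (2.95 ± 0.38). The others were Hsd17b2 (2.48 ± 0.20), the cytokine signalling inhibitor Cish (2.34 ± 0.44) and the clock repressor Nr1d1 (2.14 ± 0.29). As the naming rule required, each had 3 arrays beyond all 5 of the vehicle group. Ces2c (1.49) and Abcc3 (1.48) rose. The 5 largest decreases were those of Scd (-2.78 ± 0.54), Slc6a6 (-2.73 ± 0.24), Cdkn1a (-2.11 ± 0.22), Tubb2a (-2.07 ± 0.24) and the choline kinase Chka (-1.65 ± 0.12). Cish lost its call without 110 mg/kg replicate 1 (adjusted p = 0.0503). Dusp1 was called at no other dose, where its changes ranged from 0.50 to 1.35, and it was not called between 110 mg/kg and either 55 or 220 mg/kg.

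Of the clock list, 8 of 17 measured members rose and 4 fell, 8 and 5 adjusted over the list alone at 110 mg/kg (adjusted p = 0.000218, and adjusted p = 0.0689 with an estimated correlation). Of the CAR and PXR targets, 6 of 24 measured members rose, 9 adjusted over the list alone (where 1 fell) (adjusted p = 5.64e-05, and adjusted p = 0.199 with an estimated correlation). Of the PPAR alpha targets, 6 of 33 measured members fell, 9 adjusted over the list alone (adjusted p = 0.00350, and adjusted p = 0.381 with an estimated correlation), among them Pdk4 (-1.35) and Angptl4 (-1.47). Of the endoplasmic reticulum and integrated stress response list, 3 of 26 measured members rose, 9 adjusted over the list alone (adjusted p = 0.00128, and adjusted p = 0.310 with an estimated correlation). Of the stellate cell markers, 1 of 18 measured members fell, 1 adjusted over the list alone (median -0.18, adjusted p = 0.0114, and adjusted p = 0.424 with an estimated correlation). Limma called 0 of the endothelial markers (2 were lower at an unadjusted p under 0.05), and the list passed downward (median -0.29, adjusted p = 0.0185, and adjusted p = 0.644 with an estimated correlation). Without 110 mg/kg replicate 3 the 2 lists reached adjusted p-values of 0.438 and 0.807, and without vehicle replicate 1 the endothelial list reached 0.0745. In fry neither these lists (adjusted p = 0.163 and 0.382) nor the PPAR alpha (0.0676) and endoplasmic reticulum lists (0.0564) passed. In all, 513 genes changed in limma's test, 336 rising and 177 falling. The count was 212 without 110 mg/kg replicate 1, 231 without replicate 3, 321 without replicate 2 and 300 without vehicle replicate 4.

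At the lowest dose, 55 mg/kg, clock genes already differed from vehicle. The 5 largest increases were those of Dbp (3.74 ± 0.27, adjusted p = 4.28e-07), the steroid-oxidising Hsd17b2 (2.44 ± 0.20), the clock repressors Nr1d1 (2.38 ± 0.29) and Per3 (1.75 ± 0.23), and Cish (1.65 ± 0.44) (log2 change ± SE, 3 against 5 arrays). Cish lost its call without any 1 of the arrays compared (adjusted p = 0.0668 without vehicle replicate 5 to 0.190 without 55 mg/kg replicate 3) and under 4 other settings (0.0527 to 0.124). The 5 largest decreases were those of Cdkn1a (-2.24 ± 0.22, adjusted p = 1.09e-05), Egr1 (-2.07 ± 0.29), Slc6a6 (-1.84 ± 0.24), Tubb2a (-1.79 ± 0.24) and Lpin1 (-1.57 ± 0.25), a phosphatidate phosphatase. Bmal1 fell by 1.29, Ces2c rose by 1.18, and Abcc3 (0.41 ± 0.33, adjusted p = 0.610) was not called.

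Of the clock list, 6 of 17 measured members rose and 3 fell, 7 and 5 adjusted over the list alone at 55 mg/kg (adjusted p = 0.0133, and adjusted p = 0.129 with an estimated correlation). The call was lost with a minimum log2 of 6 (adjusted p = 0.0741) and with only these 2 groups in the fit (0.115). Of the CAR and PXR targets, 4 of 24 measured members rose, 4 adjusted over the list alone (adjusted p = 0.0227, and adjusted p = 0.394 with an estimated correlation), a call lost without vehicle replicate 3 (adjusted p = 0.0691) or 55 mg/kg replicate 3 (0.0995), with a minimum log2 of 6 (0.0526) and in fry (0.0502). Limma called 0 of the stellate cell and endothelial markers at this dose (4 and 2 were lower at an unadjusted p under 0.05). Both lists passed downward, with medians of -0.17 (adjusted p = 0.00848, and adjusted p = 0.415 with an estimated correlation) and -0.21 (adjusted p = 0.0389, and adjusted p = 0.682 with an estimated correlation). Without 55 mg/kg replicate 3 they reached adjusted p-values of 0.171 and 0.296. The endothelial list also lost its call without vehicle replicate 1, 2 or 4 or 55 mg/kg replicate 2 (adjusted p = 0.0586 to 0.153) and under 3 other settings (the lowest 0.0613). In fry neither list passed (adjusted p = 0.241 and 0.541). In all, 400 genes changed in limma's test, 275 rising and 125 falling. The count was 127 without 55 mg/kg replicate 2, 158 without replicate 3, 193 without replicate 1 and 221 without vehicle replicate 2 or 4, and 648 with 881 mg/kg replicate 2 left out of the shared estimate of the spread.

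**Figure D3:**
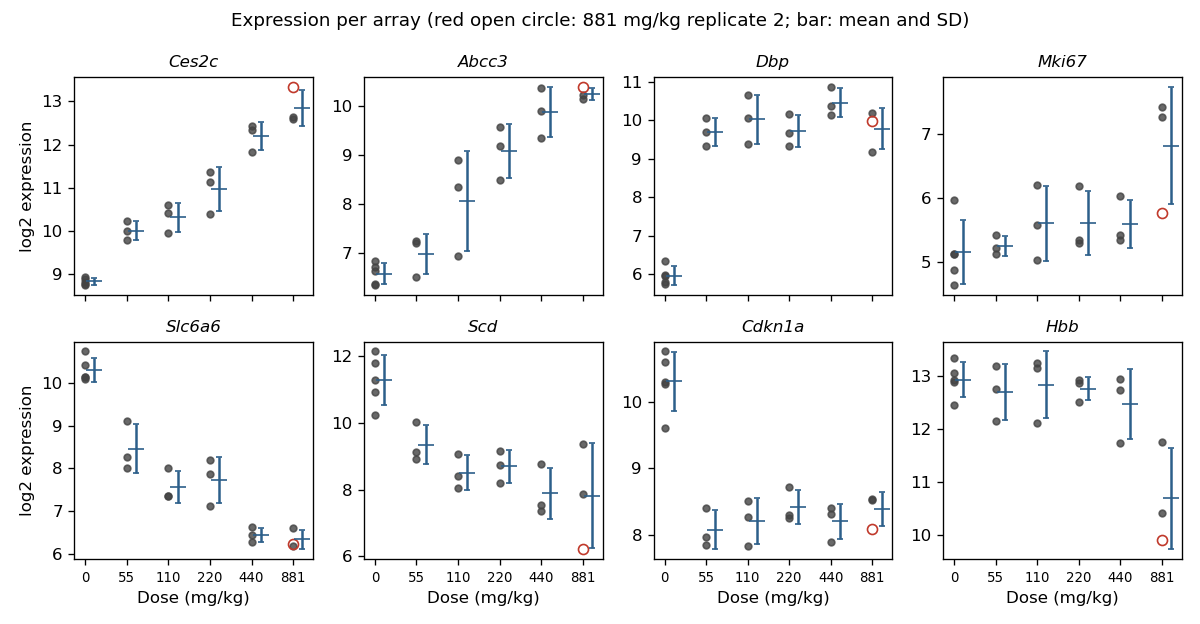
Log2 expression (vertical axes) of Ces2c, Abcc3, Dbp, Mki67, Slc6a6, Scd, Cdkn1a and Hbb on each array, by dose in mg/kg (horizontal axes); horizontal marks with bars give the mean and SD of each group, and the red open circle is 881 mg/kg replicate 2. Dbp was 3.74 above vehicle at 55 mg/kg and 3.83 above it at 881 mg/kg, whereas Ces2c was 1.18 and 4.03 above.

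From 440 to 881 mg/kg, Osgin1, an NRF2 target, rose by 1.35 ± 0.17 (log2 change ± SE, 3 against 3 arrays, adjusted p = 0.00376). Pdk4 (1.90 ± 0.31, adjusted p = 0.0186), Nfil3 (1.55 ± 0.26, adjusted p = 0.0186), Tubb2a (1.49 ± 0.27) and Pnrc1 (1.13 ± 0.22) were the other genes with the largest increases. Serpina7 (-1.72 ± 0.35, adjusted p = 0.0426), Lpin1 (-1.39 ± 0.28), Tob2 (-1.01 ± 0.19), the organic anion transporter Slc22a8 (-0.93 ± 0.17) and the sulfotransferase Sult1c3 (-0.77 ± 0.13) showed the largest decreases. Osgin1 was 1.14 below vehicle at 440 mg/kg and not called against it at 881 mg/kg (0.21). Pdk4, Nfil3 and Tubb2a were also below vehicle at 440 mg/kg (-3.12, -2.10 and -2.53) and less so at 881 mg/kg (-1.22, -0.56 and -1.04). Against vehicle at 881 mg/kg, Nfil3 was not called and Tubb2a was no longer called without replicate 2 (adjusted p = 0.0540). Serpina7 was not called at 440 mg/kg against vehicle. In all, 37 genes changed between these doses, 19 rising and 18 falling, and 1510 had an unadjusted p under 0.05. The count was 1 without 440 mg/kg replicate 1 or 3, 17 without 881 mg/kg replicate 3, 19 without 440 mg/kg replicate 2 and 114 without 881 mg/kg replicate 2. Osgin1 was the 1 of these 10 genes called whichever array was left out: the others reached an adjusted p of 0.0957 (Pdk4) to 0.251 (Lpin1) without 440 mg/kg replicate 1. With only these 2 groups in the fit, none of the 10 was called (adjusted p = 0.170 to 0.508).

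Over the dose steps from vehicle to 881 mg/kg, the genes with the smallest p were again Ces2c and Abcc3, which rose by 0.79 ± 0.039 and 0.79 ± 0.056 per step (log2, SE, 20 arrays, adjusted p = 1.20e-11 and 8.06e-09). Ugt2b1 (0.32 ± 0.024), which conjugates with glucuronic acid, Topbp1 (0.28 ± 0.022), a DNA damage response gene, and Gsta4 (0.28 ± 0.024) also rose step by step in this linear term. Slc17a4 (-0.19 ± 0.014, adjusted p = 9.02e-09), the tight junction gene Cldn1 (-0.28 ± 0.022), Slc6a6 (-0.78 ± 0.068), kynureninase Kynu (-0.23 ± 0.021) and glycine N-methyltransferase Gnmt (-0.23 ± 0.021) fell.

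Of the CAR and PXR targets, 15 of 24 measured members rose and 1 fell, 16 and 1 adjusted over the list alone with dose (adjusted p = 8.82e-12, and adjusted p = 0.0689 with an estimated correlation). Of the NRF2 targets, 15 of 22 measured members rose, 18 adjusted over the list alone (adjusted p = 1.63e-11, and adjusted p = 0.0689 with an estimated correlation). Of the cholesterol synthesis genes, 15 of 20 measured members rose, 15 adjusted over the list alone (adjusted p = 8.63e-08, and adjusted p = 0.278 with an estimated correlation). Of the Kupffer cell and macrophage markers, 13 of 14 measured members fell, 14 adjusted over the list alone (adjusted p = 2.69e-09, and adjusted p = 0.218 with an estimated correlation). Of the pericentral markers, 8 of 13 measured members fell, 9 adjusted over the list alone (adjusted p = 1.20e-05, and adjusted p = 0.158 with an estimated correlation). The clock list did not pass for the trend (adjusted p = 0.141). In all, 3087 genes changed with the dose step, 1835 rising and 1252 falling, and 2415 without 881 mg/kg replicate 2. With each array centred on its median, 1559 rose and 1578 fell. Without the whole 881 mg/kg group the count was 1829, and without the vehicle group it was 1274.

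**Figure D4:**
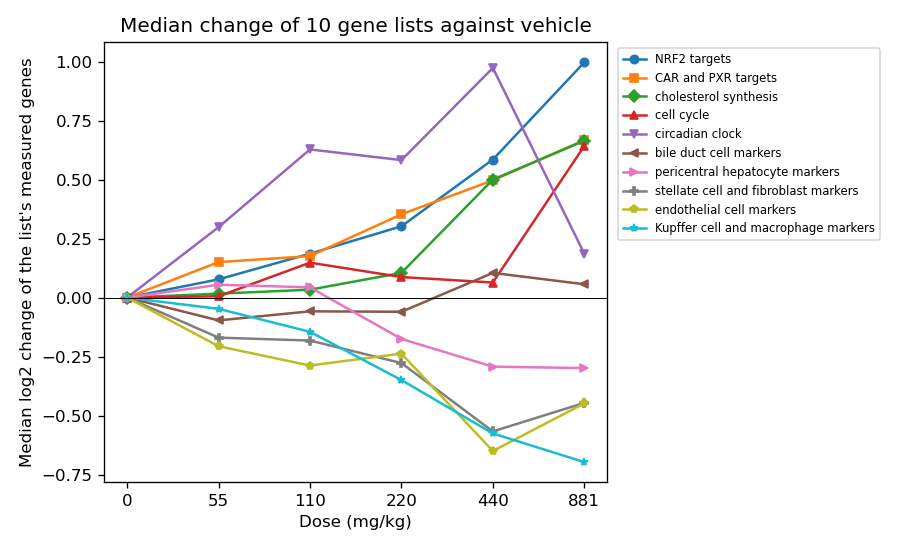
Median log2 change against vehicle (vertical axis) of the measured members of 10 gene lists at each dose in mg/kg (horizontal axis). The NRF2 list's median reached 0.996 at 881 mg/kg, and the Kupffer cell and macrophage list's median was -0.58 at 440 mg/kg and -0.70 at 881 mg/kg.

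Log2 changes at 440 and 881 mg/kg correlated across genes with r = 0.802 and rho = 0.757; genes are not independent replicates. Both doses were set against the same vehicle arrays, and unchanged groups simulated against those arrays gave a mean r of 0.375 (0.334 to 0.413 over 100 runs). With the vehicle arrays split between the doses, r had a median of 0.697 (0.672 to 0.735 over 20 splits). The observed covariance was 0.0745, the simulated one 0.00662, and their difference, 0.0678, estimates the shared effect. Of the genes, 718 rose at both doses and 378 fell at both, where independent lists would share 122.3 and 41.0, a figure that leaves out the shared vehicle arrays. The 2 changes had the same sign for 78.4% of genes, against 62.3% in the simulation. Over all doses, 133 genes were called in 1 direction at each of the 5.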

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

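The correlations that test both explanations for 881 mg/kg replicate 2 were chosen before their results were seen, and the tests of the clock genes and of the cell type markers were chosen after the results were seen.

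On 881 mg/kg replicate 2 the Gapdh control gene read 5.24 higher at its 3' than at its 5' end, in control probe sets that no comparison uses, and the array correlated least with the others. Across genes, its difference from the other 881 mg/kg arrays correlated with a slope on the beta-actin 3' minus 5' difference. That slope came from the 17 arrays of the other groups, and r was 0.422 (0.351 to 0.437 with any 1 of them left out). RNA degradation predicts this, and genes are not independent replicates. At 55, 110, 220 and 440 mg/kg, however, replicate 2 also had the highest beta-actin difference of its group (2.52, 2.41, 2.72 and 2.61). Arrays with the same replicate number deviated together somewhat (median r 0.136). Something shared by the arrays numbered 2 could thus give such an r too, so the test cannot single out degradation. The difference of 881 mg/kg replicate 2 also correlated with the change at 440 mg/kg, r = 0.231 (0.170 to 0.254 with any 1 vehicle or 440 mg/kg array left out). A stronger response to the dose in that sample cannot be told apart. The lowest of these values fell under the 0.2 set for it and none under the 0.1 set against it. Degradation and a stronger response may hold together in 881 mg/kg replicate 2. Without this array 23 named genes lost their call at 881 mg/kg, and more cell cycle genes were called than with it.

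Clock genes already differed from vehicle at 55 mg/kg. Along the axis of the clock list's change at 110, 220 and 440 mg/kg, the 881 mg/kg arrays lay 1.05 times as far from the vehicle mean as the 55 mg/kg arrays (0.962 to 1.16 with any 1 array left out), and along that of 110, 220 and 881 mg/kg the 440 mg/kg arrays lay 1.36 times as far (1.30 to 1.42), which argues against growth by over 1.5 times from 55 mg/kg but not against a smaller growth up to 440 mg/kg; a ratio of median absolute changes, 1.14 (95% bootstrap interval 0.256 to 2.04), had been tried before it and did not settle the question. Vehicle arrays varied along the clock axis with an SD of 0.527, against a median of 0.205 for random lists of the same size and mean level, and a share of 0.0466 of those lists varied as much, but without vehicle replicate 2 the SD was 0.163 and the share 0.653, so that spread rests on 1 array. Tissue collected from vehicle and dosed rats at different times of day may give such a step, and it cannot be told apart from an effect of any dose because collection times are not given in the sources used here. An effect of the treatment already present at 55 mg/kg stays open and untested.

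Markers of Kupffer, stellate and endothelial cells were lower at 440 and 881 mg/kg, with medians over their 47 members of -0.575 and -0.570, and the stellate and endothelial lists also passed at 55, 110 and 220 mg/kg and the Kupffer list at 220 mg/kg, though at no dose with an estimated correlation (adjusted p = 0.191 or more with an estimated correlation) and in fry neither for any of them below 440 mg/kg (adjusted p = 0.111 or more) nor for the endothelial list at 440 or 881 mg/kg (0.0588 and 0.114). Without 881 mg/kg replicate 2 the median at 881 mg/kg was -0.503 (95% bootstrap interval -0.632 to -0.383), which argues against the RNA quality of that array as the cause. The medians of the 3 lists at 440 mg/kg differed by at most 0.0830, and every pairwise interval held 0. A larger share of hepatocyte RNA in the tissue sampled predicts this. The intervals ran as far as -0.306 and 0.361, past the 0.3 set against that explanation, so they cannot decide for it. All intervals here come from resampled genes, which are not independent replicates, and do not measure the spread between samples. At 881 mg/kg the medians differed by up to 0.251, or 0.332 without replicate 2, with an interval of -0.416 to -0.0911 for Kupffer less endothelial markers with all arrays, so there a larger hepatocyte share cannot be told apart from a change in Kupffer cells, because the difference set against it, 0.3, was passed only without that array. Bile duct markers do not decide it, since several lie near the lowest signals and Epcam, at a log2 change of 0.86, rose, and lower expression within those cells, or fewer of them after treatment, stays open and untested.

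In the vehicle group, 12 of 132 values tested had 1 array far from the other 4, by a rule that chance meets in about 1 of 20 groups. The gap to the nearest array, as a share of the group's range, was 0.820 for Angptl4 and 0.773 for Apoc3 (both replicate 5), 0.879 for Prc1 (replicate 5), 0.844 for Chka and 0.838 for Epcam (both replicate 3), 0.723 for Gsta4 (replicate 4) and 0.743 for Sult1c3 (replicate 1). On replicate 2 it was 0.797 for Cldn1, 0.787 for Hsd17b2, 0.722 for Lss, 0.789 for Nr1d1 and 0.730 for Rprm. Nr1d1 read 7.72 (log2) on replicate 2 and 6.39 to 6.67 on the other vehicle arrays.

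Probe sets outside the gene tests also changed at 881 mg/kg against vehicle. Of those assigned to several genes, 1371076_at rose by 3.39 and 1370583_s_at by 1.44, and 1371102_x_at fell by 2.44 and 1371245_a_at by 2.20. Of those with no gene named here, 1397924_at rose by 2.54 and 1398566_at by 2.27, and 1395536_at fell by 1.91 and 1392613_at by 1.89. In all, 57 of 436 probe sets with several genes (36 rose, 21 fell) and 775 of 9780 with none (487 rose, 288 fell) were called.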

How the results depend on the processing

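The beta-actin covariate and the model without 881 mg/kg replicate 2 were chosen after the results were seen; all other alternatives were planned. Of 187 changes of named genes run under the alternatives, none reversed its direction with a call in the main or the alternative model. Sign changes of genes called in neither were not counted. C8h11orf54 and the values of genes named outside the largest changes at lower doses were not rerun. Apart from leaving out single arrays, the alternatives within 1.5 times of the reported value were counted. They were 9 of 11 at 881 mg/kg, 10 of 12 at 440 mg/kg, 8 of 12 at 220 mg/kg and 9 of 12 at 110 mg/kg. They were 8 of 12 at 55 mg/kg, 8 of 11 between 440 and 881 mg/kg, 10 of 13 for the trend and 8 of 9 for the lists. All 6 for the correlation lay in that band too, but a correlation cannot rise past 1, so the band tests little there. A minimum change of 1.5-fold, stricter by construction, left 719 genes at 881, 506 at 440, 175 at 220, 190 at 110 and 131 at 55 mg/kg, and 628 for the trend. At 55 mg/kg 64 of those rose and 67 fell, against 275 and 125 without the minimum. Array quality weights raised the count to 2511 at 440, 1293 at 220, 800 at 110 and 842 at 55 mg/kg and to 174 between 440 and 881 mg/kg; the cause was not tested. With only the arrays of the groups compared, and so fewer samples, 1795 genes were called at 881 mg/kg and 0 by limma between 440 and 881 mg/kg, where 1510 had an unadjusted p under 0.05 in the shared model. The covariate gave 780 genes at 110 and 678 at 55 mg/kg and 68 between 440 and 881 mg/kg, for a cause that was not tested. Leaving 881 mg/kg replicate 2 out of the shared model gave 748 at 220 and 648 at 55 mg/kg. That array takes no part in the log2 changes at these doses, so the rise came through the shared estimate of the spread. With fewer samples, the trend had 1829 genes without the 881 mg/kg group and 1274 without the vehicle group. At 881 mg/kg 0 of the lists passed camera with the correlation estimated for each list, and 22 passed fry, a separate test. The correlation of changes at 440 and 881 mg/kg was 0.897 over genes called at 881 mg/kg and 0.697 with the vehicle arrays split. The excess of rising genes depends on the scaling. With a quantile normalization run again and with each array centred on its median, the share that rose went from 65.4% to 56.3% and 52.6% at 881 mg/kg, from 61.2% to 54.5% and 55.8% at 440 mg/kg, from 65.6% to 59.0% and 56.5% at 220 mg/kg, from 65.5% to 54.2% and 55.3% at 110 mg/kg, from 68.8% to 53.7% and 57.1% at 55 mg/kg and from 59.4% to 52.6% and 49.7% for the trend. Between 440 and 881 mg/kg, where 19 rose and 18 fell, it was 20 and 28, and 18 and 28.

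Leaving out 1 array, with the lone pair of a dosed group assumed to vary like the other groups, gave 1643 (without 881 mg/kg replicate 2) to 2725 genes at 881 mg/kg, 867 (440 mg/kg replicate 2; 945 without replicate 3) to 1434 at 440 mg/kg, 204 (220 mg/kg replicate 2) to 457 at 220 mg/kg, 212 (110 mg/kg replicate 1) to 481 at 110 mg/kg and 127 (55 mg/kg replicate 2) to 391 at 55 mg/kg. It gave 1 (440 mg/kg replicate 1 or 3) to 114 (881 mg/kg replicate 2) between 440 and 881 mg/kg, 2415 to 3117 for the trend, 14 (881 mg/kg replicate 3) to 17 lists and a correlation of 0.754 to 0.812. The cholesterol synthesis list at 55 mg/kg was the 1 result that reversed with a call in either model. It passed camera in the other direction without 55 mg/kg replicate 1 (adjusted p = 0.0137). With all arrays its adjusted p was 0.678. It passed in the original direction without replicate 2 (adjusted p = 0.0200) and reached up to 0.924 without other arrays; the cause was not tested. Of the 118 named genes called at 881 mg/kg, 87 were called whichever array was left out.

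The replicate numbers were tried as a replicate block, which gave 322 genes at 220 mg/kg and moved no other count by over 1.5 times. Of 45 pairs of arrays with the same number, 28 deviated together with r over 0.1, and the lowest r was -0.116. Their median r was 0.136, against -0.0498 for other pairs from different dose groups. What the numbers stand for is not given in the sources used here, so a shared batch or day can be neither shown nor set aside. Of 18 arrays, 15 correlated best with their own number, a hint from the data and not from the design. Arrays give no read depth: low signals, compressed by background correction, limit what can be seen.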

Other observations

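The tests of other groupings of the arrays, the comparisons between dosed groups other than 440 and 881 mg/kg, and the genes singled out in this part were chosen after the results were seen.

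Osgin1, an NRF2 target, did not follow the dose. It was 1.14 below vehicle at 440 mg/kg (log2, adjusted p = 9.63e-05), where it read 10.28, 10.73 and 10.90 on the 3 arrays against 11.58 to 12.12 on the vehicle arrays. At 220 and 881 mg/kg it measured 0.046 and 0.21 (adjusted p = 0.919 and 0.373). From 220 to 440 mg/kg it fell by 1.19 (adjusted p = 0.0223). Limma called 3 genes between these doses (834 had an unadjusted p under 0.05). The others were Noct, up by 2.44 (adjusted p = 0.0305), and C8h11orf54, up by 0.68 (adjusted p = 0.0305). The count was 7 without 881 mg/kg replicate 2 in the shared model.

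The 3 lowest doses were not told apart gene by gene. Limma called 0 genes between 55 and 110 mg/kg (387 with an unadjusted p under 0.05), 0 between 55 and 220 mg/kg (619) and 0 between 110 and 220 mg/kg (417). The unadjusted counts were 2.72%, 4.35% and 2.93% of 14217 genes, each under the share of 0.05 that no difference would give on average. Between 55 and 440 mg/kg limma called 147 genes, with 73 higher and 74 lower at the higher dose. Between 55 and 881 mg/kg it called 1004, with 577 higher and 427 lower. These counts were 301 and 685 without 881 mg/kg replicate 2. Over all doses, 3437 genes were called against vehicle at 1 dose or more, 1598 of them at 881 mg/kg alone. A clock axis was drawn from the vehicle mean, set to 0, to the mean of the 55 mg/kg arrays, set to 1. Along it the vehicle arrays lay at -0.061, 0.160, -0.0022, -0.034 and -0.064, and every dosed array at 0.790 to 1.30. The gap between vehicle and 55 mg/kg is thus fixed by construction and tests nothing. This axis differs from those on which the distances of the 440 and 881 mg/kg arrays were given above.

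The blood genes Hbb and Alas2 varied among the dosed arrays. Hbb read 11.75, 9.92 and 10.41 (log2) on the 881 mg/kg arrays, 11.73 to 12.94 at 440 mg/kg and 12.44 to 13.34 in the vehicle group. Alas2 read 6.64, 5.30 and 5.90 at 881 mg/kg and 7.29 to 8.41 in the vehicle group.

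Other groupings of the same arrays into groups of the same sizes gave far fewer calls. At 881 mg/kg the real grouping gave 2767 genes and the highest of the others 17, at 440 mg/kg 1570 and 1, at 220 mg/kg 488 and 1, at 110 mg/kg 513 and 1, and at 55 mg/kg 400 and 1. Each rests on 56 groupings, of which the real 1 alone gave as many, a share under 0.05, so chance alone is an unlikely source of each count. Most other groupings mix vehicle and dosed arrays, which widens the spread and lowers their counts, so the size of the gap is no measure. The 5 counts share the vehicle arrays and are not separate tests. The trend had 3087 genes with the real doses and at most 0 in limma's test with the doses exchanged. The 100 groupings counted include the real 1, and chance alone is an unlikely source there too. Of the gene lists, 17 passed at 881 mg/kg with the real grouping and at most 15 with another, with a median of 6 over the 56. The real grouping alone gave as many, a share under 0.05, but the margin was narrow. Another grouping gave 14 too, the count left without 881 mg/kg replicate 3, and 0 lists passed camera with an estimated correlation. The grouping with 15 set vehicle replicates 2, 4 and 5 against all 881 mg/kg arrays together with the other vehicle arrays. A grouping with 14 did the same with vehicle replicates 1, 2 and 4. Such groupings keep part of the dose difference in reverse, so the narrow margin does not measure chance. Given the estimated correlations, chance is still not firmly excluded for the count of 17, and still less for any single list. Between 440 and 881 mg/kg the real grouping gave 37 genes and the highest of the others 10, and 10 groupings are too few for a share under 0.05.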
